A study of Mus musculus with 18 samples.

How the data were processed

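Total RNA of chronic lymphocytic leukemia (CLL) cells from TCL1-transgenic mice was sequenced in 18 libraries, prepared with a stranded total RNA kit after column extraction. These mice carry the TCL1 oncogene and develop a B cell leukemia that is used as a model of CLL. CD49d is the integrin alpha 4 chain, encoded by Itga4. By the genotype labels, both Itga4 alleles were floxed in all mice, and the CD49d-deficient mice carried Cre in 1 Cd19 allele. The label of the CD49d-expressing mice gives this locus as +/+, which was read as no Cre allele. Cells came from spleen, with 5 libraries of each genotype, and from the peritoneal cavity, with 4 of each. Groups were taken from the titles and, for 1 title that names no tissue, from the source label. How the leukemic cells were separated from other cells is not given in the sources used here.

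The deposited table holds expected counts, estimated per gene and not whole, for 55891 Ensembl gene IDs in the 18 libraries. Per the labels the authors used Salmon and the genome build mm10, and no versions, annotation release or filters are given in the sources used here. All columns were used. Of all values between 0 and 20, only 3 were whole to within 1e-06, while every column summed to a whole number to within 0.11. The values therefore look scaled within a library, and the counting error they carry is not exactly that of whole reads. The values were rounded to whole counts before testing. Totals ran from 60.36 to 111.1 M counts per library, and between 15729 and 17679 genes per library had at least 10 counts. Gene symbols and positions came from the GENCODE M21 annotation of mm10, matched by gene ID without version, since only 35 IDs matched with their version. A symbol was found for 51425 IDs. The 4466 IDs without one stayed in the library sizes and tests and held 2.94% to 8.44% of the counts of a library. Counts are estimated fragments without molecular identifiers, so intervals of shares cover counting error only.

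Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr on the fitted groups, robust dispersions, two-sided). Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Each genotype comparison within a tissue used the libraries of that tissue alone. The tissue comparisons and the difference of the genotype effects between tissues used all 18 libraries in 1 fit, so a gene's counts per M (CPM) can differ slightly between the fits. Itga4 and Cd19 were also compared with an exact two-sided permutation test of log2(CPM + 1). Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison, leaving out lists with fewer than 3 tested genes. The same test with an estimated correlation, and fry, stood beside it. The symbol Aldoa stood for 2 gene IDs, so the glycolysis and hypoxia list of 25 symbols held 26 IDs.

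Groups, tests, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The 30 lists were BCR signalling, immediate early and BCR-induced genes, heat shock, actin cytoskeleton and synapse, integrins and adhesion, chemokine receptors and migration, cell cycle, MYC targets and ribosome biogenesis, NF-kB targets, BCL2 family and survival, interferon response, antigen presentation, oxidative phosphorylation, glycolysis and hypoxia, cholesterol biosynthesis, B-1 and CLL phenotype, plasma cell, and mitochondrially encoded and sex-linked genes. Marker lists covered T cells, NK and cytotoxic cells, macrophages and monocytes, large peritoneal macrophages, red pulp macrophages, neutrophils, erythroid cells, platelets, mast cells, dendritic cells and stromal cells. The rule named Itga4, Cd19 and the integrin chains Itgb1 and Itgb7 throughout. It also named, among called genes with a mean CPM of at least 1, the 10 with the smallest p in each direction and up to 4 called members of each list. Without calls it took the 4 genes with the smallest p as values. Of the genes it names, those in the text were picked after their values were seen, with preference for calls that held when each library was left out in turn. In the CD49d-expressing tissue comparison 49 of 84 named calls held in all of these fits, and in the CD49d-deficient one 57 of 96. Genes past the test only when adjusted over their list alone, and the list members given as examples in the genotype comparisons, were added after their values were seen.

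Replicates were compared first: over 32 pairs within groups the chi-square of the counts was 203 to 670 times its degrees of freedom, so no library was a copy of another. The library names carry numbers, 8 of which occur in both tissues. After removal of the group means, the spleen and peritoneal libraries of a number correlated with r from 0.193 to 0.495, above 0.1 in all 8 pairs. Each of these 8 spleen libraries correlated best with the peritoneal library of its own number. The labels do not call the number a mouse, so the block was an alternative: with the library number as replicate block over all libraries the tissue comparisons called 2252 genes in CD49d-expressing and 2521 in CD49d-deficient cells, and the difference between tissues called 0. Replicate numbers of the titles did not pair the libraries. Nothing in the labels gives a sequencing batch.

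Most alternatives changed 1 choice: DESeq2 size factors or total counts in place of TMM, the Wald test of DESeq2 1.42.0 (with its own size factors), limma-voom, no count filter or a stricter one, non-robust dispersions, a fold threshold, antigen receptor segments left out, covariates for markers of other cells or for Xist, other sets of libraries in the fit, replicate blocks, and each library left out in turn. The block in complete pairs also left out the other groups and unpaired libraries, and 1 DESeq2 fit also left out a library. Covariates for macrophage markers and for heat shock genes, fits without 1 or 2 libraries that stood apart, and the effect correlation without Itga4 and Cd19 were chosen after seeing the data. Every comparison was repeated on regrouped libraries. The test was also tried on data simulated from these libraries, with 100 genes changed 2-fold, 100 changed 4-fold and 1 list shifted 1.5-fold. There edgeR recovered 26% of 2-fold and 73% of 4-fold changes in spleen, 11% and 67% in the peritoneal cavity, and 7% and 53% for a difference between tissues. In the tissue comparisons it recovered 30% and 81% (CD49d-expressing), and 36% and 82% (CD49d-deficient). In spleen, DESeq2 recovered 62% and 89%, with 76 false calls against 4 of edgeR. The shifted list, oxidative phosphorylation, was recovered in all 5 comparisons. The simulated genes were drawn independently, while the estimated correlation of this list was 0.196 in spleen and 0.337 in the peritoneal cavity. The simulation therefore does not show how often lists pass by chance in the real data. Its many changed genes also loosen the Benjamini-Hochberg cutoff. The recoveries of genes can therefore overstate those in a comparison with few or no changed genes.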

Results

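The leukemic cells of TCL1-transgenic mice were profiled from 2 tissues and 2 genotypes. Spleen gave 5 CD49d-deficient and 5 CD49d-expressing libraries, and the peritoneal cavity gave 4 of each. CD49d is the alpha 4 chain of the integrins VLA-4 (with beta 1, Itgb1) and LPAM-1 (with beta 7, Itgb7), through which B cells adhere to fibronectin, VCAM-1 and MAdCAM-1. Totals were 66.23 to 111.1 M counts in the CD49d-expressing and 60.36 to 110.2 M in the CD49d-deficient spleen libraries. They were 64.86 to 87.95 M and 71.06 to 78.52 M in the peritoneal ones. The labels number replicates but do not say that each is a separate mouse, so p-values measure the spread between these libraries. Errors are SD over libraries for CPM and SE of the fit for log2 fold changes.

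Itga4, the deleted gene, had the smallest p between genotypes in both tissues. In spleen its level was 3.19 ± 1.84 CPM (SD, n = 5) in CD49d-deficient and 210 ± 35.1 CPM (n = 5) in CD49d-expressing cells, a 65.8-fold difference. In the peritoneal cavity it was 11.2 ± 12.3 CPM (n = 4) and 410 ± 77 CPM (n = 4), a 36.8-fold difference. No library of one genotype overlapped the other, and the exact permutation p was 0.00794 in spleen and 0.0286 in the peritoneal cavity, the smallest these group sizes allow. Cd19, the B cell co-receptor whose locus carries Cre in the deficient mice, was 516 ± 132 against 731 ± 128 CPM in spleen (exact permutation p = 0.00794) and 436 ± 54.5 against 849 ± 152 CPM in the peritoneal cavity (exact permutation p = 0.0286). The genotypes therefore differ in CD49d, in Cre and in Cd19 level, and no comparison here separates these. An effect of CD49d loss named below is the difference between these genotypes. For the partner chains no difference was called, which does not show equal levels. Itgb1 had a log2 fold change of 0.16 (SE 0.14) in spleen and -0.41 (SE 0.30) in the peritoneal cavity, and Itgb7 of -0.30 (SE 0.28) and -0.05 (SE 0.16). Of simulated 2-fold changes 26% and 11% were recovered in these comparisons, in data with many more changed genes. Itga4 (ENSMUSG00000027009.19) lies on chromosome 2 at 79255426 to 79333123, plus strand, and Cd19 (ENSMUSG00000030724.8) on chromosome 7 at 126408450 to 126414889, minus strand, in mm10. Both values count fragments over the whole gene, and which part of Itga4 is floxed is not given in the sources used here.

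**Figure D1:**
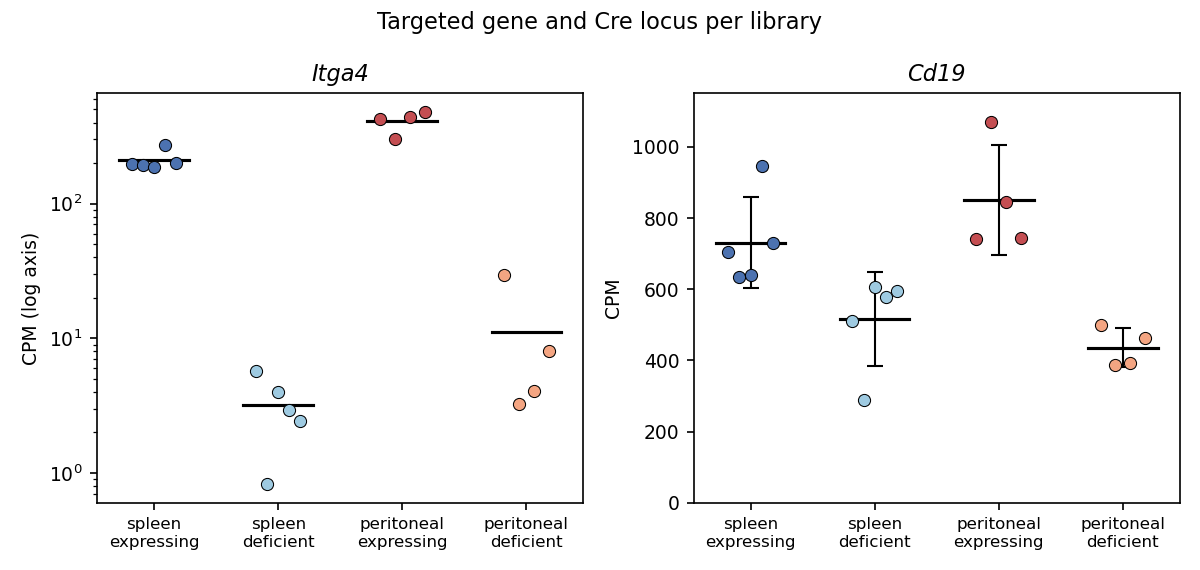
CPM of Itga4 (left, log axis) and Cd19 (right, linear axis) in each library, by tissue and genotype. Points are libraries, horizontal lines are group means and error bars on the right are SD (n = 5 in spleen, n = 4 in the peritoneal cavity). Every CD49d-deficient library has less Itga4 (at most 29.3 CPM) than any CD49d-expressing one (at least 187 CPM).

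Between the genotypes in spleen, Itga4 was the only called gene (log2 fold change -6.04, SE 0.47, adjusted p = 0.00165) among 16435 tested by edgeR. For genes of the processes named in the study's title no difference beyond the spread between libraries was called. The recovery of 26% for simulated 2-fold changes came from data with many more changed genes and can overstate what was detectable here. In the actin cytoskeleton and synapse list 0 of 60 genes were called, with a median log2 fold change of 0.01 (camera adjusted p = 0.682). Its members Rac2, a Rho GTPase of blood cells, and Vasp, an actin filament elongation factor, had log2 fold changes of -0.11 (SE 0.13) and 0.06 (SE 0.19). In the BCR signalling list 0 of 32 were called, with a median of 0.06 (adjusted p = 0.645). There Pik3r1, a regulatory subunit of PI3 kinase, had 0.07 (SE 0.20) and Inpp5d, which encodes the inhibitory phosphatase SHIP1, 0.11 (SE 0.15). Unadjusted, 1187 genes had p below 0.05 in spleen, against 822 under chance. DESeq2 called 143 genes (21 higher, 122 lower) and limma-voom 1, and on simulated changes DESeq2 also made more false calls than edgeR. Without CD49d-deficient replicate 3 edgeR called 2 genes, and without CD49d-deficient replicate 4 it called 3.

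The spleen lists that passed were mostly markers of other cells, lower in the CD49d-deficient group. Neutrophil markers were lower in all 11 tested genes (median log2 fold change -2.60, adjusted p = 2.34e-06), among them Ngp (-2.83, SE 1.22) and S100a8 (-2.59, SE 1.29). CD49d-expressing replicate 3 held much of this RNA, with Ngp at 140 CPM (7.82 to 21.5 CPM in the other 4) and S100a8 at 74.8 CPM (4.36 to 8.79 CPM), and the list still passed without it. Macrophage and monocyte markers (median -0.66, adjusted p = 0.00282), NK and cytotoxic markers (-0.88, adjusted p = 0.0036) and red pulp macrophage markers (-1.55, adjusted p = 0.0358) were lower too. Cholesterol biosynthesis was the only list that passed upward, with 19 of 21 genes above 0 and a median of 0.30 (adjusted p = 0.00011). Insig1, a sterol-regulated member, had 0.43 (SE 0.32). With an estimated correlation all 5 lists had an adjusted p of 0.513, and by fry 0.253 to 0.342. Without CD49d-deficient replicate 2 the NK list had 0.0524 and the red pulp list 0.19. Without CD49d-deficient replicate 4 the macrophage and red pulp lists both had 0.0789, and the red pulp list had 0.099 and 0.171 without CD49d-expressing replicates 2 and 3. Adjusted over the list alone, 1 gene of the chemokine receptor list, Rgs16 (-4.52, SE 1.05), and 1 of the BCL2 family list, the proapoptotic Bmf (-1.73, SE 0.34), were lower, and 0 in the others. The 23 remaining lists had adjusted p from 0.0653 to 0.873.

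In the peritoneal cavity edgeR called 0 of 16905 genes between genotypes. Itga4 had the smallest p (log2 fold change -5.20, SE 0.77, adjusted p = 1), followed by Cd19 (-0.96, SE 0.17), Lef1 (4.92, SE 0.94) and Lyz1 (1.92, SE 0.38). Lef1, a transcription factor of the Wnt pathway, was 8.36 ± 6.49 CPM in CD49d-deficient (SD, n = 4) and 0.272 ± 0.26 CPM in CD49d-expressing cells (n = 4). Lyz1, a lysozyme, was 20.5 ± 5.97 and 5.41 ± 2.24 CPM. The spread of Itga4 came from CD49d-deficient replicate 1, with 29.3 CPM. Without this library Itga4 was called (log2 fold change -6.33, adjusted p = 0.0147), as it was with all 18 libraries in the fit (adjusted p = 0.0136). Unadjusted, 454 genes had p below 0.05, against 845 under chance. DESeq2 called 20 genes (7 higher, 13 lower), including Cd19 and Lef1 but giving no adjusted p for Itga4, and limma-voom called 0.

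Immediate early and BCR-induced genes, which B cells switch on after antigen receptor engagement, were lower in CD49d-deficient peritoneal cells as a list, with 24 of 29 genes below 0, a median log2 fold change of -0.27 and an adjusted p of 0.0213. Fos (-0.66, SE 0.31) and Nr4a3 (-1.68, SE 1.05) were examples. NK and cytotoxic markers were the other list to pass (median -1.62, adjusted p = 0.000123). Both had an adjusted p of 0.896 with an estimated correlation and 0.962 by fry. The immediate early list had 0.462 and 0.101 without CD49d-expressing replicates 2 and 4, and 0.0791 and 0.274 without CD49d-deficient replicates 2 and 3. Actin and synapse genes (median 0.01, adjusted p = 0.884) and BCR signalling genes (median -0.04, adjusted p = 0.334) did not pass. Adjusted over the list alone, 1 gene passed, Lef1 in the B-1 and CLL phenotype list. The 25 remaining lists had adjusted p from 0.0701 to 0.925.

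The effect of CD49d loss was then tested for a difference between the tissues, and edgeR called 0 of 18219 genes. Unadjusted, 557 had p below 0.05 against 911 under chance. DESeq2 called 11 genes (9 higher, 2 lower) and limma-voom 0. Among named genes with a mean of at least 1 CPM, the smallest p values belonged to Gprc5b (log2 difference 5.18, SE 1.34), Vopp1 (2.98, SE 0.82), Pdlim3 (2.88, SE 0.81) and Dst (4.76, SE 1.35). Dst was 21.2 ± 20.8 CPM in CD49d-expressing spleen (SD, n = 5) and 0.715 ± 0.481 to 2.04 ± 1.76 CPM in the other groups. Among lists, neutrophil (median difference 6.23, adjusted p = 1.1e-09), red pulp macrophage (1.21, adjusted p = 0.00116), erythroid (6.07, adjusted p = 0.00116), macrophage and monocyte (1.34, adjusted p = 0.00051) and large peritoneal macrophage markers (1.42, adjusted p = 0.024) had a more positive CD49d effect in the peritoneal cavity. Heat shock (-0.50, adjusted p = 0.024) and cholesterol biosynthesis genes (-0.37, adjusted p = 0.00196) had a more negative one. The 23 remaining lists had adjusted p from 0.0581 to 0.989. With an estimated correlation the lowest adjusted p of the 7 was 0.544, and by fry 0.901. Adjusted over the list alone, 7 neutrophil, 9 erythroid and 2 red pulp genes (Slc40a1 and Vcam1) were higher. Several of these had counts in 1 of the 4 peritoneal CD49d-deficient libraries alone, replicate 1, with Ngp at 8.05, S100a9 at 3.75, Camp at 1.68, Alas2 at 0.768 and Slc40a1 at 1.56 CPM there and 0 in the others, examples chosen after their values were seen. Peritoneal CD49d-expressing libraries were at or near 0 for them, so the neutrophil and erythroid medians are fitted values near the floor and not measured folds. Across 18219 genes the 2 tissues' CD49d effects correlated with Pearson's r = 0.342 and Spearman's rho = 0.27 over the 8 library numbers with both tissues. Genes are not independent replicates, and 24 of the 35 splits of these numbers gave an r as high (exact permutation p = 0.686).

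Removal of libraries moved several of these lists across the threshold. The macrophage list had an adjusted p of 0.111 and the erythroid list 0.49 without peritoneal CD49d-deficient replicate 1, whose markers of both stand highest in its group. Cholesterol biosynthesis had 0.323 without peritoneal CD49d-expressing replicate 1 and 0.0977 without peritoneal CD49d-deficient replicate 4. Heat shock lost its call without each of 6 libraries, up to 0.387 without peritoneal CD49d-expressing replicate 1, and had 0.126 with the library number as replicate block. Large peritoneal macrophage markers also lost it without each of 6, up to 0.399 without peritoneal CD49d-deficient replicate 4, and had 0.113 with the block. The neutrophil and red pulp lists kept theirs in all of these fits.

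The tissue of origin made a far larger difference than the genotype. In CD49d-expressing cells 922 genes were higher and 803 lower in the peritoneal cavity than in spleen, of 18219 tested, and in CD49d-deficient cells 1360 were higher and 1470 lower. Of these, 591 were higher in both genotypes, against 68.8 if the calls were independent, and 554 lower in both, against 64.8. No gene was called in opposite directions. In 5 of the 8 library numbers with both tissues the leading Ighv gene differed between them, so these comparisons may also compare different B cell clones. With total counts in place of TMM the balance in CD49d-deficient cells became 2064 higher and 844 lower, and the median log2 fold change of all genes rose from 0.06 to 0.22. In CD49d-expressing cells it became 1075 and 701, with a median of 0.10 in place of 0.05. With only the compared groups in the fit 1652 and 1240 genes were called, and with the library number as replicate block in the complete pairs of those groups 876 and 1616.

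**Figure D2:**
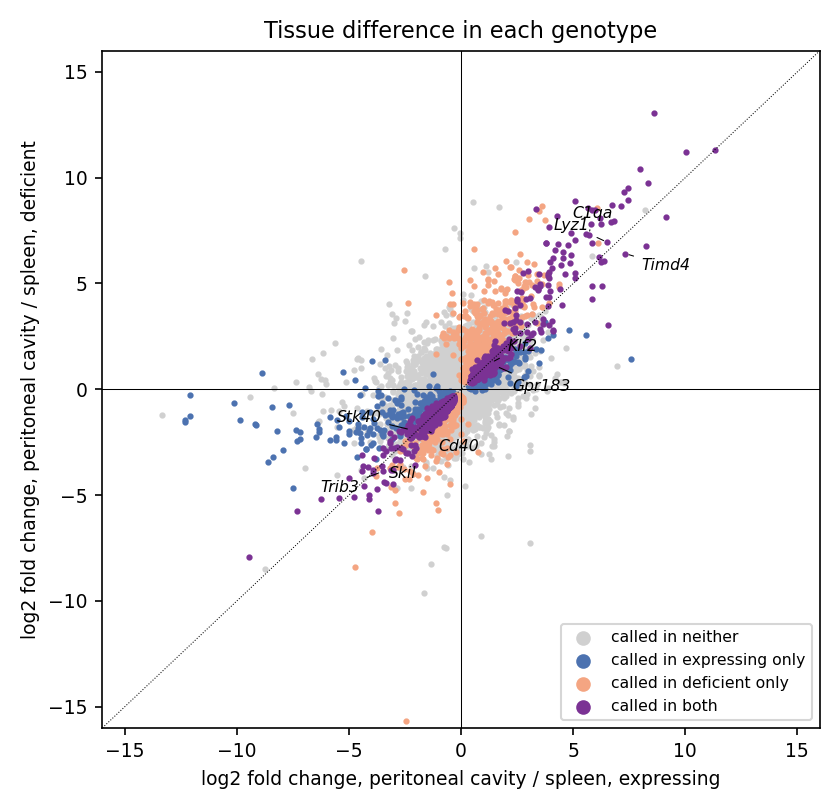
Log2 fold change between peritoneal cavity and spleen for every tested gene, in CD49d-expressing cells (horizontal axis) and CD49d-deficient cells (vertical axis), colored by the genotype in which it was called. The dotted line marks equal values. Genes called in both (591 higher, 554 lower) lie in the upper right and lower left.

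Genes for B cell surface receptors and trafficking changed in both directions, and neither list that covers them passed by camera, which tests for a shared direction. Fry for changes in either direction gave adjusted p of 3.9e-09 and 2.86e-09 (BCR signalling, CD49d-expressing and CD49d-deficient). For chemokine receptors it gave 5.84e-12 and 3.03e-12. Since 20 and 19 of the 30 lists passed that test, it does not set these lists apart. Gpr183, the oxysterol receptor EBI2 that guides B cells within lymphoid tissue, was 31.7 ± 5.22 CPM in CD49d-expressing spleen (SD, n = 5) and 92 ± 10.2 CPM in the peritoneal cavity (n = 4), a log2 fold change of 1.54 (SE 0.20), and it rose by 1.11 (SE 0.20) in CD49d-deficient cells. Klf2, a transcription factor of lymphocyte quiescence and trafficking, rose by 1.32 (SE 0.24) and 1.24 (SE 0.24). Gna13, a G protein subunit that confines B cells, was lower (-0.74, SE 0.15, and -0.99, SE 0.15), and so was the homing receptor Cxcr4 (-2.01, SE 0.49, and -1.81, SE 0.49). Cd22, an inhibitory co-receptor, rose 2.85-fold (CD49d-expressing) and 2.33-fold (CD49d-deficient), and Ms4a1, which encodes CD20, rose 2.09-fold and 1.54-fold. Pik3r1 rose 2.29-fold and 2.30-fold, while Inpp5d fell to 297 ± 5.7 CPM from 603 ± 103 CPM in CD49d-expressing and to 304 ± 33.1 from 664 ± 100 CPM in CD49d-deficient cells. In the BCR signalling list 6 genes were higher and 1 lower in CD49d-expressing cells, and 3 and 3 in CD49d-deficient cells (adjusted p = 0.275 and 0.969). The chemokine receptor list had 2 higher and 3 lower, then 2 and 4 (adjusted p = 0.737 and 0.592). The Cxcr4 call was lost without peritoneal CD49d-expressing replicate 2 or 4 (adjusted p = 0.0535 and 0.0585) and, in CD49d-deficient cells, without spleen replicate 2 or peritoneal replicate 1 or 2 (0.0511 to 0.0601). The Cd22 call of CD49d-deficient cells was lost without spleen replicate 2 (0.0515) or peritoneal replicate 4 (0.0857), and that of Ms4a1 without spleen replicate 1 or 2 or peritoneal replicate 2 or 3 (0.0521 to 0.0626).

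Adhesion and cytoskeleton genes moved in both directions. Of all tested genes 9.47% were called in CD49d-expressing and 15.5% in CD49d-deficient cells, and the share of the actin and synapse list was near these. Itgb1 rose 2.23-fold in the peritoneal cavity of CD49d-expressing mice (833 ± 323 against 374 ± 52.8 CPM, adjusted p = 0.00581) and had a fold of 1.48 in CD49d-deficient cells (adjusted p = 0.0931), a log2 difference between genotypes of -0.59 (SE 0.31) that was not called. Itgb1 was called in CD49d-deficient cells too with the library number as replicate block (0.58, adjusted p = 0.0428), with limma-voom and an estimated correlation within library numbers (0.0361) and with total counts (0.0319). Itga4 itself had a log2 fold change of 0.87 (SE 0.53, adjusted p = 0.315) in CD49d-expressing cells. It was called there with only the compared groups in the fit (adjusted p = 0.0182) and with the library number as replicate block in their complete pairs (0.0368). Limma-voom with an estimated correlation within library numbers (0.0436) and the covariate for other cells (0.0363) also gave a call. With the macrophage covariate it turned to -0.55 (0.571). That covariate had 1 slope for both genotypes, so the turn does not show that macrophage RNA made the rise. In the fits of each tissue, CD49d-expressing libraries held 300 to 478 CPM in the peritoneal cavity and 187 to 272 CPM in spleen. Peritoneal CD49d-deficient libraries held at most 29.3 CPM. The residual Itga4 of CD49d-deficient cells was higher in the peritoneal cavity (log2 fold change 1.69, SE 0.55, adjusted p = 0.046), a call lost without spleen CD49d-deficient replicate 2, 3, 4 or 5 or peritoneal CD49d-deficient replicate 1 or 4 (0.0626 to 0.374). Without peritoneal CD49d-deficient replicate 1 the log2 fold change was 0.58. The Itga4 call was also lost with the library number as replicate block (0.96, adjusted p = 0.123, or 0.219 in complete pairs of the compared groups) and with only these groups in the fit (0.153). It was lost with limma-voom (0.125, or 0.0731 with an estimated correlation within library numbers) and without the count filter (0.0895). The covariates for other cells (log2 fold change 0.86, adjusted p = 0.172), Xist (1.60, 0.0619) and heat shock (1.88, 0.172) ended the call too. With the macrophage covariate its direction turned (-1.04, 0.472). Itgb7 had 0.61 (SE 0.25, adjusted p = 0.137) in CD49d-expressing cells, called with limma-voom and an estimated correlation within library numbers (adjusted p = 0.0461). In CD49d-deficient cells it had 0.84 (SE 0.25, adjusted p = 0.036), a call lost without spleen CD49d-deficient replicate 1, 3 or 5 or any of the 4 peritoneal CD49d-deficient replicates (0.0505 to 0.0838). Rac2 rose by 0.55 (SE 0.15) and 0.73 (SE 0.15), and Gmfg, a glia maturation factor that remodels branched actin, by 1.26 (SE 0.26) and 1.24 (SE 0.26). Vasp was lower (-0.86, SE 0.19, and -1.23, SE 0.19). Of 60 actin and synapse genes, 3 were higher and 2 lower in CD49d-expressing cells and 6 and 4 in CD49d-deficient cells (adjusted p = 0.543 and 0.969), or 8 and 3, then 7 and 4, adjusted over the list alone. Of 34 integrin and adhesion genes, 3 were higher and 2 lower, then 5 and 4 (adjusted p = 0.93 and 0.969). The Rac2 call of CD49d-expressing cells was lost without spleen replicate 2, 4 or 5 or any of the 4 peritoneal replicates (adjusted p from 0.0505 to 0.0691).

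NF-kB targets were lower in the peritoneal cavity in both genotypes. Of 22 genes, 6 fell and 0 rose in CD49d-expressing cells (median log2 fold change -0.61, adjusted p = 3.68e-05), and 9 fell and 0 rose in CD49d-deficient cells (median -0.83, adjusted p = 2.27e-05). Their adjusted p was 0.457 and 0.488 with an estimated correlation, and 0.0234 and 0.0101 by fry. Cd40, the costimulatory receptor, had log2 fold changes of -1.58 (SE 0.26) and -1.92 (SE 0.27), and Relb, a subunit of NF-kB, was 2.04-fold and 2.48-fold lower. Nfkb1 was 1.84-fold lower in CD49d-expressing cells, and Traf1 and Rel were 3.60-fold and 3.22-fold lower in CD49d-deficient cells. Tnip1, a partner of the NF-kB inhibitor A20, was 2.27-fold lower in CD49d-deficient cells. Other genes with the smallest p were also lower. Skil, which restrains TGF-beta signaling, was 521 ± 45.7 CPM in CD49d-expressing spleen (SD, n = 5) and 93.8 ± 18.8 CPM in the peritoneal cavity (n = 4). It was 5.55-fold lower there and 8.19-fold lower in CD49d-deficient cells. Stk40 was 4.64-fold and 3.79-fold lower. Trib3, Sesn2 and Nars were lower as well, with log2 fold changes in CD49d-expressing cells of -3.50 (SE 0.48), -2.39 (SE 0.28) and -1.38 (SE 0.16).

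**Figure D3:**
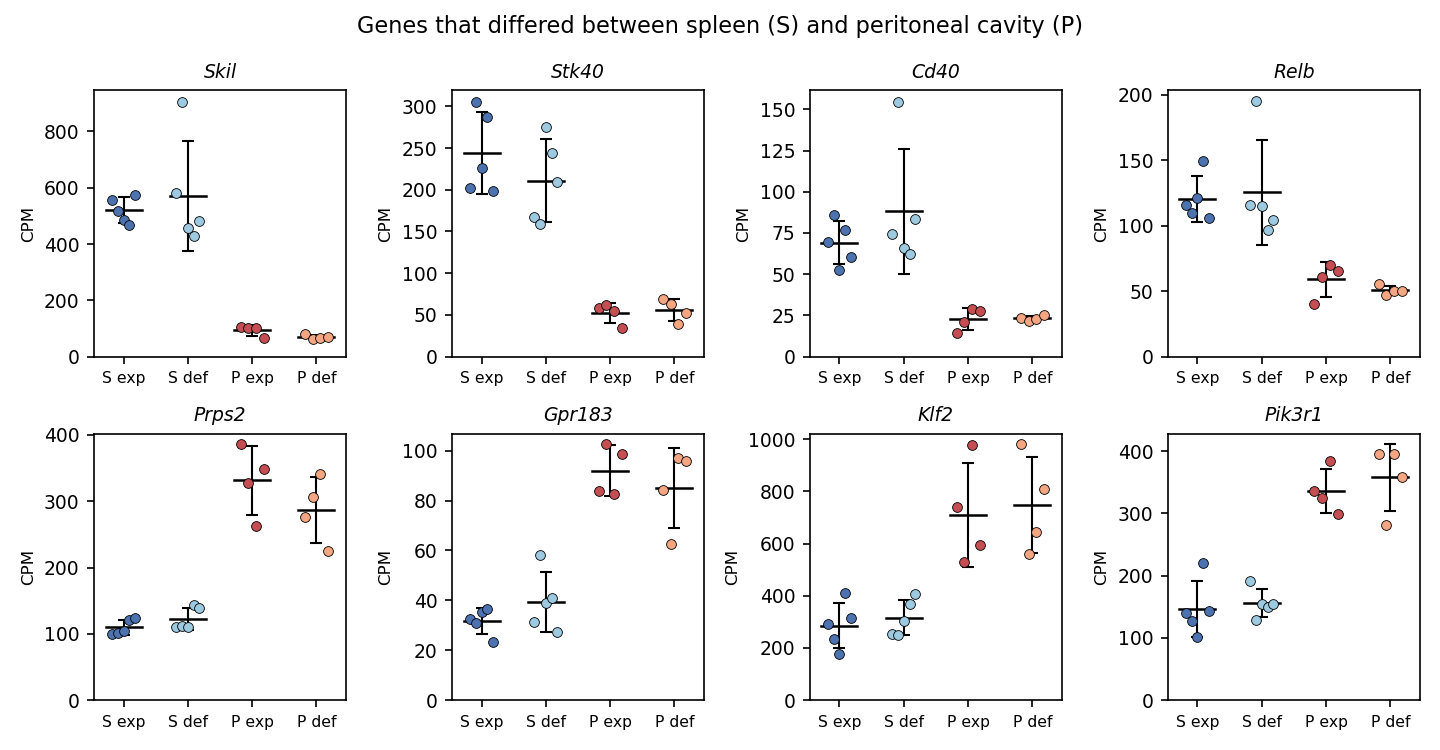
CPM (linear axes from 0) of Skil, Stk40, Cd40, Relb, Prps2, Gpr183, Klf2 and Pik3r1 in each library, by tissue (S, spleen; P, peritoneal cavity) and genotype (exp, CD49d-expressing; def, CD49d-deficient). Points are libraries, lines are means and error bars are SD (n = 5 in spleen, n = 4 in the peritoneal cavity). In both genotypes the first 4 genes are lower and the last 4 higher in the peritoneal cavity.

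Stress and early response genes split by gene. Heat shock genes were lower in the peritoneal cavity (median log2 fold change -0.84 and -0.99 in CD49d-expressing and CD49d-deficient cells, adjusted p = 0.0139 and 0.000136, or 0.758 and 0.577 with an estimated correlation and 0.322 and 0.0771 by fry). Of 15 genes 1 and 5 were called lower. The chaperone Hspa1a was 6.35 ± 5.69 CPM in CD49d-deficient peritoneal cells (n = 4) against 364 ± 414 CPM in spleen (n = 5). The immediate early list did not pass (adjusted p = 0.124 and 0.0505). Fos was 7.81-fold higher in CD49d-expressing peritoneal cells, while Nr4a3, an orphan receptor induced by antigen receptor signals, had log2 fold changes of -3.71 (SE 1.09) and -5.75 (SE 1.21) and Tnfaip3 was 3.73-fold lower in CD49d-deficient cells. The cytokine gene Il10 was 7.73-fold and 10.2-fold lower. The heat shock list of CD49d-expressing cells lost its call without spleen replicate 1 (adjusted p = 0.136) or peritoneal replicate 2 or 3 (0.0507 and 0.0857). Without spleen replicate 1, 2, 3 or 5 or peritoneal replicate 1, 3 or 4 the Nr4a3 call of CD49d-expressing cells was lost (0.0524 to 0.103), as was that of Il10 without peritoneal replicate 4 (0.0725).

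Metabolic genes differed by pathway. Mitochondrially encoded transcripts were lower in the peritoneal cavity in all 13 genes (medians -0.75 and -0.73, adjusted p = 3.37e-05 and 0.000113, or 0.504 and 0.577 with an estimated correlation and 0.0349 and 0.0332 by fry), and 3 and 4 of them were called. They held 2.29% ± 0.41 of counts in CD49d-expressing and 2.43% ± 0.65 in CD49d-deficient spleen (SD, n = 5), and 1.47% ± 0.26 and 1.59% ± 0.20 in the peritoneal cavity (n = 4). Nuclear oxidative phosphorylation genes were higher in CD49d-expressing cells (median 0.18, 3 of 41 called, adjusted p = 0.0125, or 0.758 with an estimated correlation and 0.115 by fry), and in CD49d-deficient cells the list did not pass (median 0.16, adjusted p = 0.0631). That list had 0.0692 without spleen CD49d-expressing replicate 1 and 0.116 without peritoneal CD49d-expressing replicate 3. Among glycolysis and hypoxia genes 5 were higher and 2 lower in each genotype (adjusted p = 0.155 and 0.118, or 0.0488 and 0.029 by fry). Tpi1 rose 1.80-fold and 1.91-fold, Eno1 1.80-fold and 2.01-fold, and the hypoxia-induced Ankrd37 8.61-fold and 5.88-fold. Cholesterol biosynthesis genes were lower in CD49d-deficient cells (median -0.59, 4 of 21 called, adjusted p = 0.0041, or 0.577 with an estimated correlation and 0.0771 by fry), led by Insig1 (-1.37, SE 0.32), and did not pass in CD49d-expressing cells (adjusted p = 0.3). Prps2, a synthase of the nucleotide precursor PRPP, was 3.01-fold and 2.34-fold higher. Without peritoneal CD49d-expressing replicate 4 the Eno1 call of CD49d-expressing cells was lost (adjusted p = 0.0583).

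Cell cycle genes leaned upward in the peritoneal cavity, with 44 of 46 above 0 in CD49d-expressing (median 0.34, adjusted p = 0.00567) and 45 of 46 in CD49d-deficient cells (median 0.88, adjusted p = 0.00125), or 0.835 and 0.894 with an estimated correlation and 0.427 and 0.403 by fry. Only 0 and 2 of them were called, and 0 in either adjusted over the list alone. The list lost its call without spleen CD49d-expressing replicate 4 (0.16), peritoneal CD49d-expressing replicate 4 (0.0729) and peritoneal CD49d-deficient replicate 2 (0.445). Survival genes went both ways: Bcl2 was 1.80-fold and 1.59-fold higher, and Bbc3, which encodes the proapoptotic PUMA, 2.01-fold and 2.97-fold lower. The Bcl2 call of CD49d-deficient cells was lost without spleen replicate 2 or 5 or peritoneal replicate 1 or 3 (0.0521 to 0.0795). The Bbc3 call of CD49d-expressing cells was lost without spleen replicate 3 or 4 or peritoneal replicate 1, 2 or 4 (0.0559 to 0.0918). Of the other lists, BCL2 family (adjusted p = 0.314 and 0.347), MYC targets (0.63 and 0.701), interferon response (0.541 and 0.347), antigen presentation (0.314 and 0.969), B-1 and CLL phenotype (0.269 and 0.972), plasma cell (0.0569 and 0.093) and sex-linked genes (0.933 and 0.995) did not pass in either genotype.

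RNA of other cell types differed between the tissues along with these gene groups. Macrophage and monocyte markers were higher in the peritoneal cavity (8 and 11 of 19 genes called, adjusted p = 1.03e-05 and 1.03e-08), and so were large peritoneal macrophage markers (8 and 10 of 11 called, adjusted p = 5.15e-09 and 1.47e-10). With an estimated correlation these had 0.457 and 0.334, and 0.356 and 0.222, and by fry 0.00464 and 0.000107, and 0.000345 and 2.76e-05. The complement gene C1qa was 0.339 ± 0.113 CPM in CD49d-expressing spleen (SD, n = 5) and 17.8 ± 17.7 CPM in the peritoneal cavity (n = 4), and 0.198 ± 0.0935 against 31.1 ± 28.3 CPM in CD49d-deficient cells. Saa3 reached 141 ± 190 and 163 ± 166 CPM in the peritoneal cavity from 0.434 ± 0.535 and 0.188 ± 0.0816 CPM. Neutrophil markers were lower in the peritoneal cavity of CD49d-expressing mice (9 of 13 called, adjusted p = 2.08e-08, or 0.457 with an estimated correlation), with Ngp at 0.00551 ± 0.011 against 38.4 ± 57.2 CPM, and the list did not pass in CD49d-deficient ones (adjusted p = 0.0599). Erythroid markers (adjusted p = 0.000241, or 0.539 with an estimated correlation) and T cell markers (0.00646, or 0.457) were lower in CD49d-expressing peritoneal libraries. In CD49d-deficient ones T cell (0.0358, or 0.577) and NK markers (0.0041, or 0.577) were lower and stromal markers higher (0.0386, or 0.482). By fry these lists had 0.00958 (neutrophils), 0.0562 (erythroid cells) and 0.0321 (T cells) in CD49d-expressing and 0.0697 (T cells), 0.0805 (NK cells) and 0.0049 (stromal cells) in CD49d-deficient mice. The Ngp call was lost without peritoneal CD49d-expressing replicate 3 (0.054) and with limma-voom (0.064). The T cell call of CD49d-deficient cells was lost without spleen replicate 3 or 4 or peritoneal replicate 3 (0.0692 to 0.186), and the stromal call without spleen replicate 4 or peritoneal replicate 1, 2 or 4 (0.0652 to 0.113). Marker lists that did not pass were red pulp macrophages (0.0827 and 0.995), platelets (0.933 and 1), mast cells (0.314 and 0.972), dendritic cells (0.737 and 0.962), erythroid cells in CD49d-deficient (0.241) and NK and stromal cells in CD49d-expressing mice (0.124 and 0.224).

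**Figure D4:**
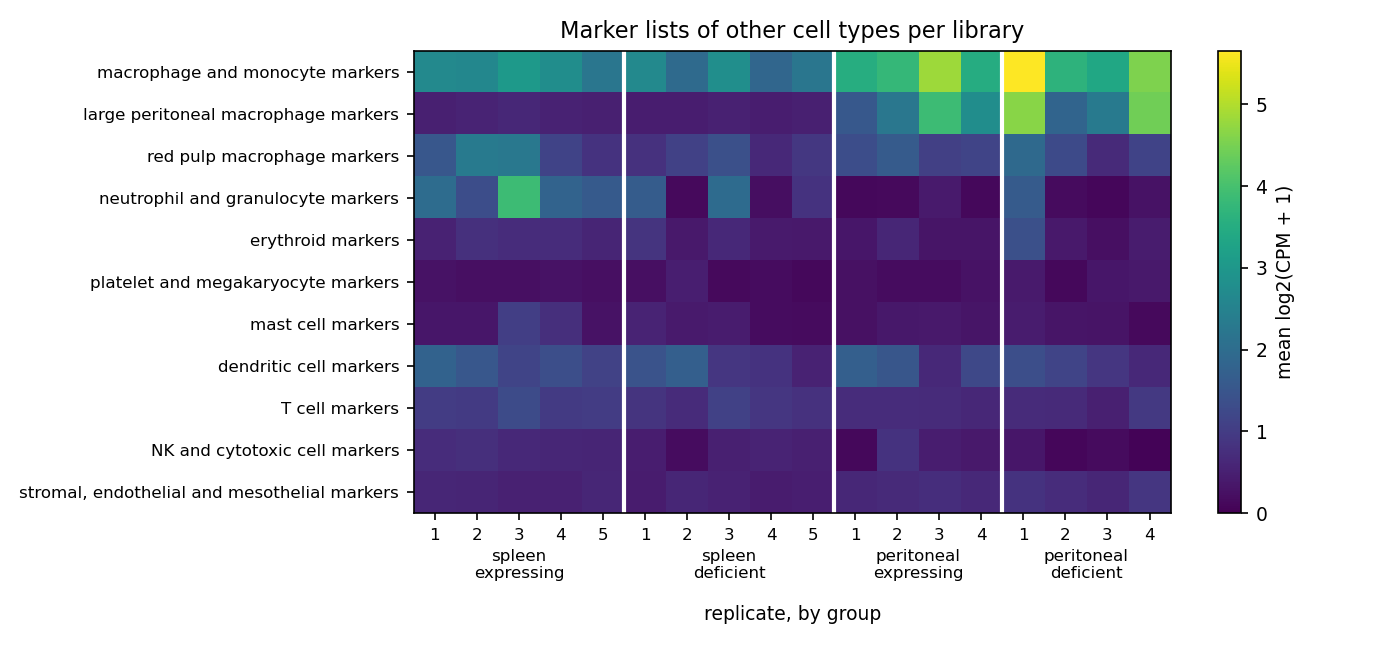
Mean log2(CPM + 1) of the marker genes of 11 other cell types (rows) in each of the 18 libraries (columns, numbered by replicate within the 4 groups), as color from 0 upward. Macrophage and monocyte and large peritoneal macrophage markers are brighter in the peritoneal libraries, red pulp macrophage markers are not, and neutrophil markers brightest in spleen CD49d-expressing replicate 3 (3.87).

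Many tissue calls changed with a covariate or with single libraries. With the mean of the macrophage markers as a covariate, a setting added after seeing the data, 757 genes were called in CD49d-expressing and 247 in CD49d-deficient cells, and among the genes named above Cd22, Nr4a3, Vasp, Rac2, Klf2, Gna13, Cxcr4, Bcl2, Eno1 and Lef1 lost their calls in CD49d-expressing cells and Itga4, Itgb7, Nars, Tnip1, Trib3, Pik3r1, Cd22, Nr4a3, Tnfaip3, Hspa1a, Vasp, Rac2, Gmfg, Gna13, Gpr183, Klf2, Cxcr4, Traf1, Rel, Bcl2, Eno1, Ankrd37, Insig1 and Ms4a1 in CD49d-deficient cells. Some lost calls had similar or larger log2 fold changes with this covariate, as in CD49d-expressing cells Vasp (-0.93), Rac2 (0.65) and Cd22 (1.44), while Klf2 (0.90) and Cxcr4 (-1.50) had smaller ones. In CD49d-deficient cells Vasp (-1.32), Rac2 (0.88) and Gmfg (1.37) had similar or larger ones and Klf2 (0.62) and Cxcr4 (-0.72) smaller ones. That of Itga4 in CD49d-deficient cells changed sign (-1.04). With the mean of the heat shock genes, also added after seeing the data, the counts were 945 and 475, and Nr4a3, Rac2, Bcl2, Eno1, Il10 and Slc40a1 lost their calls in CD49d-expressing cells and Itga4, Itgb7, Cd22, Nr4a3, Tnfaip3, Hspa1a, Rac2, Klf2, Cxcr4, Traf1, Rel, Bcl2, Tpi1, Eno1, Ankrd37, Insig1, Il10 and Ms4a1 in CD49d-deficient cells. Of these, Rac2 (0.52), Il10 (-3.23) and Slc40a1 (-8.97) had log2 fold changes in CD49d-expressing cells near or beyond those without the covariate. Those of Nr4a3 (-2.69) and Eno1 (0.66) were smaller. Hspa1a is itself part of the heat shock mean, so its lost call is no separate result. With the replicate block in the complete pairs of the compared groups Pik3r1, Nr4a3, Vasp, Rac2, Klf2, Bbc3, Ms4a1, Il10 and Lef1 lost theirs in CD49d-expressing cells and Itga4, Tnfaip3, Tpi1 and Ms4a1 in CD49d-deficient cells. Most log2 fold changes of this CD49d-expressing set were similar or larger in that fit, as for Pik3r1 (1.26), Klf2 (1.38), Nr4a3 (-4.50), Vasp (-0.82) and Ms4a1 (1.08), while that of Lef1 was smaller (-2.78). With only the compared groups in the fit Nr4a3 (log2 fold change -3.70, adjusted p = 0.0538) and Lef1 (-5.12, 0.0693) lost their calls in CD49d-expressing cells. In CD49d-deficient cells Cd22 (1.23, 0.0549), Tnfaip3 (-1.90, 0.0572), Ankrd37 (2.57, 0.0567), Insig1 (-1.37, 0.0512), Ms4a1 (0.64, 0.056) and Itga4 (1.69, 0.153) did. Left out in turn, spleen CD49d-expressing replicates 1 and 2 and peritoneal CD49d-expressing replicates 3 and 4 lowered the CD49d-expressing count to 1113, 947, 1100 and 934. Spleen CD49d-deficient replicate 2 and peritoneal CD49d-deficient replicate 4 lowered the CD49d-deficient count to 1859 and 1683. With the planned covariate for markers of other cells Nr4a3 (log2 fold change -3.78, adjusted p = 0.0539), Rac2 (0.52, 0.0648) and Bbc3 (-0.73, 0.0631) lost their calls in CD49d-expressing cells. Cxcr4 (-1.54, 0.0515) and Itga4 (0.86, 0.172) lost theirs in CD49d-deficient cells. DESeq2 called 2933 and 4065 genes.

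Clonal composition was approximated by the immunoglobulin heavy chain V genes, since a B cell clone carries 1 productive heavy chain rearrangement. Junctions were not read, so a shared V gene need not be a shared clone, and the shares are of RNA and not of cells. A single Ighv gene held from 33.2% to 99.8% of the Ighv counts of a library, and Ighv1-55 led in 8 of the 18 libraries. Ighv12-3 led in 3 and the remaining 4 leading genes in the others. Of the 8 library numbers with both tissues, 3 had the same leading Ighv gene in spleen and peritoneal cavity and 5 had different ones. In library number 106 Ighv1-55 held 99.6% in spleen and 99.8% in the peritoneal cavity, both with exact Clopper-Pearson limits equal to the value at this rounding. In library number 101 it held 95.9% in spleen (95% interval 95.7% to 96%) and 19.1% in the peritoneal cavity, where Ighv11-2 led with 74.7% (74.4% to 74.9%). Totals of 61024 to 290222 Ighv counts per library stood behind these shares.

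**Figure D5:**
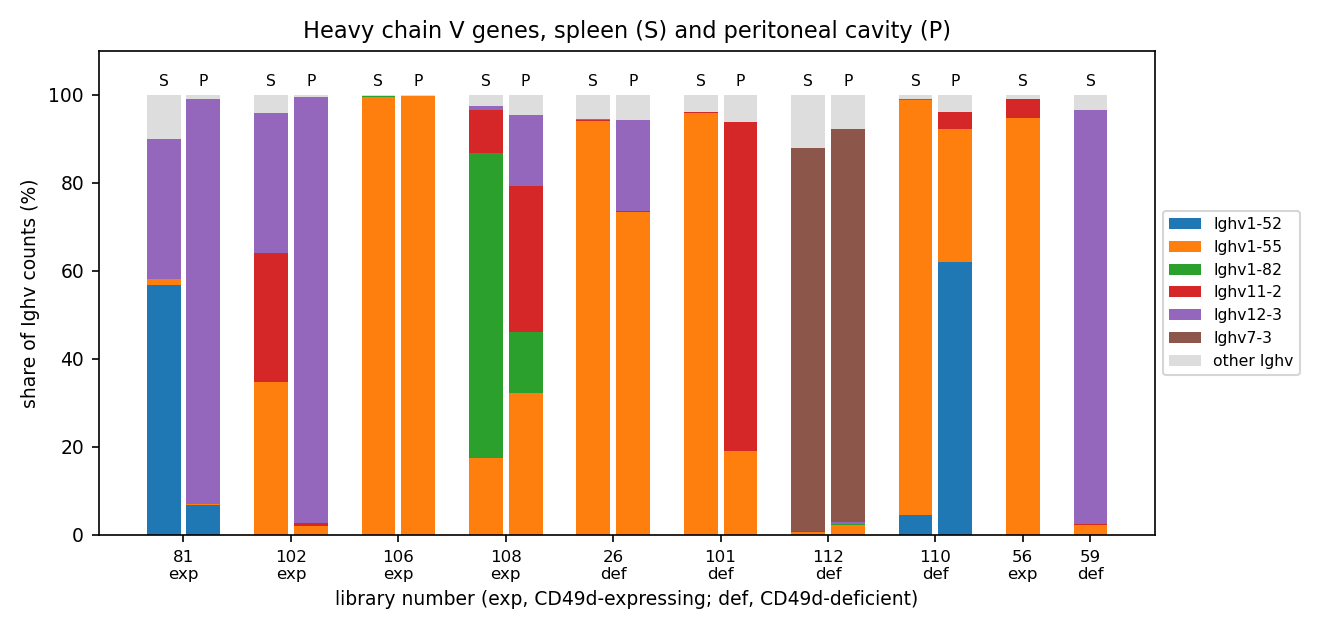
Share of Ighv counts (percent, stacked to 100) held by each of the 6 genes that lead any library, and by all other Ighv genes, in the spleen (S) and peritoneal (P) libraries of each library number and in 2 numbers with spleen alone. Number 106 is nearly all Ighv1-55 in both tissues, while number 101 changes from Ighv1-55 (95.9%) to Ighv11-2 (74.7%).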

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

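The macrophage covariate, the reading of NF-kB targets under either covariate, the Itga4 to C1q ratio and the regroupings are tests chosen after the result was seen, while the list tests and the other-cell covariate were planned and the slopes on the macrophage score were written before their result was seen. A library stood apart from its group in 31 of 387 groups of values, where chance gives about 1 in 20, or 19.4. The values below are named because the gap to the nearest other library took up most of the group's range, and the CD49d effects because their difference between the tissues passed a test.

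Libraries with other-cell RNA stood apart most often. In spleen CD49d-expressing replicate 3 the neutrophil score was 3.87 (others 1.34 to 2), the T cell score 1.29, the glycolysis and hypoxia score 5.38, S100a8 74.8 CPM, Saa3 1.39 CPM, Ankrd37 0.994 CPM (lowest) and Itpkb 219 CPM (lowest). In peritoneal CD49d-deficient replicate 1 the neutrophil score was 1.63, the erythroid score 1.37, Ngp 8.05 CPM, S100a8 4.14 CPM and Slc40a1 1.56 CPM. Peritoneal CD49d-expressing replicate 3 had a neutrophil score of 0.4 and Ngp at 0.022 CPM, and replicate 2 an erythroid score of 0.599 and Eno1 at 324 CPM (lowest).

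The other values that stood apart belonged to different libraries. In spleen these were total counts of 110 M in CD49d-deficient replicate 5, Itga4 at 281 CPM and Prg4 at 0.395 CPM in CD49d-expressing replicate 4, and Lef1 at 39.8 CPM in CD49d-expressing replicate 5. CD49d-deficient replicate 2 had the lowest Cd19 (307 CPM) and Vopp1 (0.215 CPM) and the highest Relb (195 CPM) of its group, and replicate 3 had Nars at 210 CPM. In the peritoneal cavity Cd24a was 1200 CPM in CD49d-deficient replicate 2, and Skil 65.9 CPM (lowest) and Rgs16 0.573 CPM in CD49d-expressing replicate 4. The BCR signalling score was 8.21 in CD49d-deficient replicate 4 and the B-1 and CLL phenotype score 5.08 (lowest) in replicate 3. The leading Ighv gene held 87.1% in spleen CD49d-deficient replicate 4 and 33.2% in peritoneal CD49d-expressing replicate 4, the lowest shares of their groups.

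The effect of CD49d loss differed between the tissues for 7 lists by camera with its preset correlation, at adjusted p of 0.024 (heat shock), 0.00196 (cholesterol biosynthesis), 0.00051 (macrophages and monocytes), 0.024 (large peritoneal macrophages), 0.00116 (red pulp macrophages), 1.1e-09 (neutrophils) and 0.00116 (erythroid cells). None passed with an estimated correlation (0.544 to 0.923) or by fry (0.901 to 0.99), and with the library number as replicate block heat shock (0.126) and large peritoneal macrophages (0.113) did not. Of 70 splits of the libraries 51 gave as many lists, up to 18, so chance cannot be excluded for their number.

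Genes higher in the peritoneal cavity in both genotypes included macrophage genes, and RNA of macrophages is a candidate source. Within the peritoneal groups the 8 shared large peritoneal macrophage markers had a median slope of 1.25 on a score of 8 macrophage and monocyte markers, a list that shares no gene with theirs, as such RNA needs. The 575 shared genes outside both lists had a median slope of 0.000177 (-0.00958 to 0.0409 with each library left out), against 0.502 if macrophages brought all of their rise, which argues against that source for the set as a whole, though 36 of them reached that slope. With the macrophage score as covariate their median log2 fold change went from 1.01 to 1 in CD49d-expressing and from 0.973 to 0.959 in CD49d-deficient cells, while 183 and 49 stayed called. Their median SE rose from 0.232 to 0.312 and 0.39 and fewer genes passed in all, and which of these ended the calls was not tested. A response of the leukemic cells to the tissue stays open, untested, as does a difference in how cells of each tissue were prepared. In 5 of the 8 library numbers with both tissues the leading Ighv gene also differed between them, and the tissue comparisons do not separate this.

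NF-kB targets were lower in the peritoneal cavity, and a stress response during isolation of spleen cells, read from heat shock genes, could raise them in spleen. With the heat shock score as covariate 90.3% of the median log2 fold change of the called targets was kept in CD49d-expressing (-1.30 to -1.17) and 84.9% in CD49d-deficient cells (-1.38 to -1.17), which argues against this as the whole cause. The calls fell to 3 of 6 and 3 of 9. The SE rose from 0.302 to 0.323 and from 0.349 to 0.398 while the folds fell, and these were not separated. With markers of other cells as covariate 99.6% and 107% were kept, with 5 of 6 and 8 of 9 called. This covariate averages lists that moved in opposite directions between the tissues. In CD49d-expressing libraries the macrophage and monocyte score went from 2.67 in spleen to 3.91, and the neutrophil score from 2.12 to 0.192. It could therefore hardly remove a tissue difference and does not decide whether RNA of other cells contributed. A signal from the spleen environment stays open, untested, as does any handling effect that heat shock genes do not record.

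Itga4 reads remained in peritoneal CD49d-deficient libraries, where macrophages, in which Cre under the B cell gene Cd19 should not be active, could supply them. The ratio of Itga4 to the sum of C1qa, C1qb and C1qc spanned 1.79-fold over the 4 libraries, while Itga4 itself spanned 9.04-fold (28.1, 3.11, 3.88 and 7.72 CPM, against 292, 39.9, 34.6 and 123 CPM of the C1q sum). This goes with RNA from macrophages, from 4 libraries. Spleen CD49d-deficient libraries also kept Itga4, at 3.19 ± 1.84 CPM (SD, n = 5), although their C1qa was far lower. Some Itga4 reads thus came without matching C1q. Leukemic cells that escaped deletion stay open, since no value here separates them.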

How the results depend on the processing

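Alternatives with a covariate for macrophage markers or heat shock genes and those with 1 or 2 named libraries out were chosen after seeing the data. The Itga4 and Cd19 differences between genotypes kept their direction under every alternative run. With each library left out, log2(CPM + 1) differences ran from -5.97 to -5.51 and -6.13 to -5.19 (Itga4, spleen and peritoneal cavity) and from -0.60 to -0.34 and -1.02 to -0.84 (Cd19).

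In spleen DESeq2 called 143 genes in place of 1, and 112 without CD49d-expressing replicate 3. Leaving out each library gave 1 to 3 genes, with 2 without CD49d-deficient replicate 3 and 3 without CD49d-deficient replicate 4. With the title number as replicate block 0 genes were called, Itga4 having a log2 fold change of -6.24 (adjusted p = 0.0607) there and -6.04 in the main fit. In the peritoneal cavity DESeq2 called 20 genes in place of 0, the covariate for markers of other cells 1 and all 4 groups in 1 fit 1, and leaving out each library gave 0 to 1. DESeq2 gave no adjusted p for Itga4 there. For the difference between tissues DESeq2 called 11, and leaving out each library gave 0 to 0. The cause was not tested.

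The tissue count of CD49d-expressing cells, 1725, became 844 at an absolute log2 fold change of at least 1, 2933 with DESeq2, 1077 with no count filter, 3460 with limma-voom and an estimated correlation within library numbers, 876 with the replicate block in complete pairs of the compared groups, 757 with the macrophage and 945 with the heat shock covariate, and 934 to 1401 with each library left out. That of CD49d-deficient cells, 2830, became 1246 with the same fold threshold, 1240 with only the compared groups in the fit, 1616 with the replicate block in complete pairs, 247 and 475 with the macrophage and heat shock covariates, and 1683 to 2885 with each library left out. The fold threshold asks for a larger change and the left-out fits have fewer samples. For the others the cause was not tested.

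With an estimated correlation 0 lists passed in spleen, peritoneal cavity, the difference between tissues and the tissue comparisons of either genotype. By fry for a shared direction 0, 0 and 0 passed in the first 3, 7 in the tissue comparison of CD49d-expressing and 6 in that of CD49d-deficient cells. By fry for changes in either direction these were 0, 0, 0, 20 and 19. With each library left out 4 to 10, 2 to 9, 5 to 11, 8 to 12 and 9 to 13 lists passed.

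The Itga4 difference between tissues changed sign to -0.62 with the other-cell and -0.48 with the macrophage covariate, -0.25 with 2 libraries out and -0.29 without peritoneal CD49d-deficient replicate 1 (up to 1.15 with other libraries left out). With the macrophage covariate the tissue effect of Itga4 became -0.55 in CD49d-expressing and -1.04 in CD49d-deficient cells and that of Cd19 -0.086 in CD49d-expressing cells, where it was -0.015 with the heat shock covariate and -0.0082 without peritoneal CD49d-expressing replicate 2 (up to 0.24 with others left out). The peritoneal Itgb7 effect became 0.021 and 0.014 without CD49d-expressing replicate 2 and CD49d-deficient replicate 4 (down to -0.16 with others left out). The cause was not tested. Of 2177 values for 84 called genes of the CD49d-expressing tissue comparison 1848 kept their direction and call, as did 2020 of 2487 for 96 genes in CD49d-deficient cells. Depth limits genes near the floor, such as Ngp at 0.00551 CPM in peritoneal CD49d-expressing libraries.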

Other observations

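Every test in this part was chosen after the result was seen. Libraries were regrouped to ask how often other splits give counts as large. For the single gene called in spleen, 6 of 100 splits gave as many (highest other 1), so chance cannot be excluded for the count. The count ignores which gene is called. Here it was Itga4, the deleted gene, whose difference this regrouping does not test. For the 143 genes of DESeq2 in spleen, 9 of 40 gave as many (highest other 339), so chance cannot be excluded, and on simulated spleen data DESeq2 made 76 false calls against 4 of edgeR. For the peritoneal cavity and the difference between tissues the count was 0, which any split reaches (35 of 35 and 70 of 70, highest other 5 and 1), so the regrouping decides nothing there.

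For the tissue comparisons no other split tried gave as many genes. In CD49d-expressing cells 1 of 100 splits, the real one, gave 1725 genes (highest other 87), and in CD49d-deficient cells 1 of 100 gave 2830 (highest other 1627). The splits with 87 and 1627 each part 3 of the 4 pairs of library numbers. Each sets 4 spleen libraries against 1 spleen library and the 4 peritoneal ones, nearly the real comparison reversed. Among the 12 and 13 other splits that part all 4 pairs the highest counts were 0 and 58. With so few of these splits a fraction below 0.05 was out of reach, so they do not exclude chance by themselves.

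For the number of lists past the test chance cannot be excluded. As many lists were given by 91 of 100 splits in spleen (5, highest other 14), 34 of 35 in the peritoneal cavity (2, highest 17), 36 of 100 for tissue in CD49d-expressing (10, highest 15) and 22 of 100 in CD49d-deficient cells (10, highest 16). For the correlation of CD49d effects between tissues, 24 of 35 splits gave an r as high (0.342, highest other 0.54).

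Ighv use was compared within library numbers, since a number may stand for 1 animal. The mean share of Ighv counts in common was 55.7% within numbers and 21.4% over other pairings, and 2 of 576 pairings within genotypes gave a share as high (exact permutation p = 0.00347). Each group held libraries with Xist and libraries with the Y-linked Ddx3y, so both sexes were present. Spleen CD49d-deficient replicate 1 had Xist at 2612 and Ddx3y at 0.0319 CPM, and replicate 3 had 0.3745 and 131.1 CPM. Y-linked expression was alike in both tissues for 8 of the 8 library numbers, which goes with 1 animal per number. The labels do not say what the number stands for.

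A gene ID without a symbol led every library, with 1.432% to 6.333% of its counts.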
